A study of Mus musculus with 6 samples.

How the data were processed

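Polyadenylated RNA of mouse LPCs was sequenced in 6 libraries with a stranded kit in paired-end mode, per the labels' protocols. Per the submitters' processing notes the tools were Trimmomatic, HISAT2, Cufflinks, HTSeq and DESeq and the genome build was mm10; their versions, roles, order, settings and annotation are not given in the sources used here. The authors deposited 1 table per library. The Bec_LPCs tables hold whole-number counts per gene symbol, and the NPC_LPCs and Hep_LPCs tables hold counts and FPKM per gene symbol, per the file headers and values. FPKM, scaled for gene length and depth as deposited by the authors, was used only for an alternative. The setting for strand is not given in the sources used here, so genes that overlap on either strand are treated as uncertain.

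The tables were not laid out alike. The Bec_LPCs tables hold 21834 rows, among them 14 without a name (44 and 41 reads, 0.000191% and 0.000181% of the counts), and 13 mitochondrially encoded genes, of which none is in the other tables. The NPC_LPCs and Hep_LPCs tables hold 21878 rows, 27 of them with date-like names, which were left as written. Older symbols were updated with the reference's synonyms (22 in the Bec_LPCs tables, 837 in the others), after which 20577 symbols were shared, against 19763 as deposited. Shared genes held 95.4% of the counts of each Bec_LPCs library and 99.3% to 99.5% of the others. Coordinates are from GENCODE M21 on mm10 and are 1-based. A gene was taken as counted alike under any rule if it is protein-coding, shares at most 25% of its exonic length with another protein-coding gene on any strand (bedtools 2.31.1), and has no near-identical copy of at least 95% identity over 200 bases (minimap2 2.31-r1302). This restriction was chosen after the tables were seen. Its name is shorthand wherever used below, since the rule does not remove every counting difference. Of 4 broadly expressed genes near 0 in the Bec_LPCs tables that lie within the overlap limit, only 2 have a copy. Overlap with genes that are not protein-coding was not considered.

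Samples were grouped by their titles. Hep_LPCs were compared with NPC_LPCs in a fit of their 4 libraries, and Bec_LPCs with each of the others in a fit of all 6. Genes passed edgeR's filterByExpr, library sizes were scaled by TMM, and edgeR's quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest, two-sided) was used with Benjamini-Hochberg adjustment over the genes tested, calling at an adjusted p under 0.05 (edgeR 4.0.16, limma 3.58.1, R 4.3.3). A fold against a group at 0 reads is a lower bound against a floor of 3 reads per library, and bounds cover counting error only. A floor of 3 reads was 0.127 to 0.178 CPM. The alternatives were DESeq2 size factors, library size alone, no low-count filter, a filter at 10 CPM in 2 libraries, DESeq2's Wald test (DESeq2 1.42.0), limma-voom, removal of the 50 highest genes, a 2-fold minimum, the replicate number as a block, other sets of libraries in the fit, each library left out, limma on log2(FPKM + 1) and the counted-alike genes. The last of these and the FPKM fit were added after the data were seen. Mitochondrially encoded genes were in no fit, so no alternative tested their removal.

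The lists were 29, fixed before the data were examined: hepatocyte identity, xenobiotic and bile acid enzymes, urea cycle, biliary markers, progenitor and fetal liver markers, YAP and TEAD targets, Notch, WNT targets, mesenchymal and stellate, epithelial to mesenchymal transition, endothelial, macrophage, lymphocyte, mesothelial, proliferation, interferon, NF-kB, cholesterol, lipid metabolism, glycolysis and hypoxia, p53, NRF2, immediate early and dissociation, MHC class II, gastrointestinal, cilium, mitochondrial, sex-linked and erythroid genes. A list was tested with camera at a preset correlation of 0.01 on log2 CPM with a prior count of 2 where at least 3 members passed the filter, with camera's estimated correlation and with fry beside it. With an estimated correlation, camera also takes its p from the few residual degrees of freedom of the fit. A call lost under it is therefore no measure of correlation alone. The mitochondrial and erythroid lists had under 3 members past the filter in each comparison, as had the lymphocyte and MHC class II lists in Hep_LPCs against NPC_LPCs. Named genes followed a rule fixed at the same time: the 8 largest increases and 8 largest decreases among called genes with at least 32 CPM in the higher group and libraries that do not overlap, key genes of liver cell types, and up to 4 members of each list by smallest adjusted p. In both Bec_LPCs comparisons several of the largest changes by this rule were in genes where a counting difference between the tables could produce them, so the same rule was also applied to counted-alike genes, a choice made after the values were seen. Isg15 and Msln, list members named because they moved against their list, and the genes of the closing part outside this rule were also chosen after their values were seen. Results of 2 genes that the rule names are not reported here.

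The tests were tested on simulated data: counts were drawn for the real genes from the real libraries with 200 genes changed. At 2-fold, 4-fold and 16-fold 7 of 67, 47 of 67 and 65 of 66 were recovered in Hep_LPCs against NPC_LPCs, with 17 false calls among 12166 genes. Set beside the 7, 47 and 65 recovered, these 17 were a larger share of the calls than the adjusted p threshold aims at. Calls in Hep_LPCs against NPC_LPCs may therefore hold more false ones than their adjusted p states. In Bec_LPCs against NPC_LPCs the recovered numbers were 0, 40 and 66, with 7 false calls among 12578 genes, and in Bec_LPCs against Hep_LPCs 1, 44 and 65, with 1 among 12588, of the same 67, 67 and 66. These recoveries hold for so few changed genes and set no limit for the data themselves, where 3160 of 4298 calls in Bec_LPCs against Hep_LPCs were at least 2-fold and the rest smaller. Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and figures.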

Results

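RNA sequencing was compared for 3 groups of mouse liver progenitor-like cells (LPCs), with 2 libraries in each. LPCs are proliferating epithelial cells grown out of adult liver, and all 3 groups were kept in Transition and Expansion Medium (TEM). Hep_LPCs came from hepatocytes of tdTomato reporter mice that had received a virus driving Cre in hepatocytes. NPC_LPCs came from the non-parenchymal cells, the liver cells other than hepatocytes, of AlbCreERT/R26GFP mice. Bec_LPCs came from intrahepatic bile duct pieces of wild-type mice that were grown in matrigel, passaged and sorted for Epcam, so Epcam is not a finding in this group. Total counts were 22985844 and 22634867 in the Bec_LPCs libraries, 17919947 and 20625957 in the NPC_LPCs libraries, and 18123118 and 17575998 in the Hep_LPCs libraries, in order of replicate number. The labels do not say whether replicates were separate cultures or animals, so p-values measure only the spread between these samples. That spread may be technical in Bec_LPCs, while the Y-linked genes described below argue against this for Hep_LPCs. In NPC_LPCs the replicates differed across genes by a chi-square of 116 per degree of freedom, against 96.8 in Hep_LPCs and 5.71 in Bec_LPCs. These values argue against repeats of 1 RNA sample in NPC_LPCs too. Levels are given as CPM on TMM-scaled library sizes, as mean ± SD over the n = 2 libraries of a group, and shift slightly between comparisons because each fit has its own scaling. Fold changes are log2 values ± SE. The SE is the size of the fold change divided by the square root of the test's F statistic. It borrows spread across genes and is not the spread of a gene's own libraries. A gene is called where edgeR's quasi-likelihood test gave an adjusted p under 0.05.

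Replicates lay closest to each other in every group. Across genes, Pearson's r between log2 CPM of the replicates was 0.993 for Bec_LPCs, 0.957 for Hep_LPCs and 0.942 for NPC_LPCs. Genes are not independent replicates, so these values describe the libraries and carry no test. Between groups the mean r over the 4 library pairs was 0.890 for NPC_LPCs and Hep_LPCs, 0.878 for Bec_LPCs and NPC_LPCs, and 0.827 for Bec_LPCs and Hep_LPCs. The order of the first and the second turned with Spearman's correlation (0.914 and 0.916). It also turned with genes taken as counted alike under any counting rule (0.884 and 0.898), so these data do not rank those pairs. The Bec_LPCs replicates differed by a chi-square of 5.71 per degree of freedom, against 116 for NPC_LPCs and 96.8 for Hep_LPCs, so the groups did not share 1 spread. One library stood apart in its Y-linked genes. Ddx3y, an RNA helicase gene on the Y chromosome, was at 0.0593 CPM (1 read) in Hep_LPCs replicate 2 and at 60.4 CPM in Hep_LPCs replicate 1, with 72.7 to 102 CPM in the other 4 libraries. The 2 Hep_LPCs libraries are therefore not repeats of 1 RNA sample, and whether they came from separate cultures or animals stays open.

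**Figure D1:**
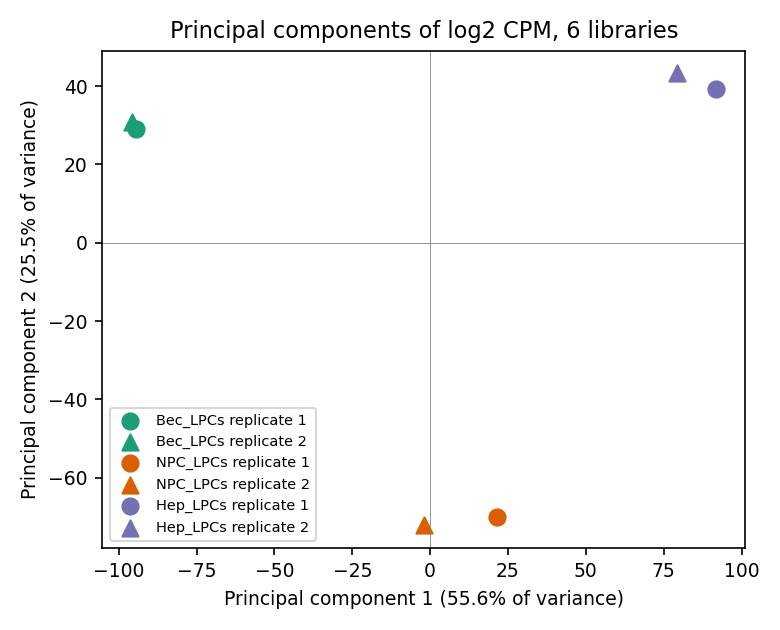
Principal components 1 (55.6% of variance) and 2 (25.5%) of log2 CPM across genes for the 6 libraries, with color for the group and symbol for the replicate. The 2 Bec_LPCs libraries lie together at one end of component 1, and the 2 libraries of each of the other groups are farther from each other than the Bec_LPCs libraries are.

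The comparison of hepatocyte-derived with non-parenchymal-derived cells is the one the growth protocol names as the purpose of the sequencing. These groups also differ in mouse line and in the virus described for Hep_LPCs. Effects of cell source cannot be told apart from these. Hnf4a, Rbp4 and Hpx, genes of hepatocytes, were higher in Hep_LPCs. Hnf4a, a transcription factor that maintains hepatocyte identity (chromosome 2, 163506808 to 163572910 in mm10), was at 242 ± 10.1 CPM in Hep_LPCs and 38.6 ± 15.9 CPM in NPC_LPCs, a log2 fold change of 2.65 ± 0.35 (adjusted p = 0.0472). Rbp4, the plasma carrier of retinol, rose by 2.73 ± 0.34 (adjusted p = 0.0409) and Hpx, the heme carrier hemopexin, by 4.41 ± 0.43 (adjusted p = 0.0315). Of the 11 tested members of the hepatocyte identity list, 3 were called higher and none lower, and 5 were higher when adjusted over the list alone (camera adjusted p = 0.00164). That list gave adjusted p = 0.713 with an estimated correlation. Alb, the albumin gene, was near 0 in both groups, with 41 and 2 reads in the Hep_LPCs libraries and 2 and 3 in the NPC_LPCs libraries, below the count filter. In total 98 of 12331 genes were called, 43 higher and 55 lower in Hep_LPCs (43.9% higher), with 2733 at an unadjusted p under 0.05. No gene was called by edgeR without Hep_LPCs replicate 1 (2062 at an unadjusted p under 0.05) or without Hep_LPCs replicate 2 (2264), while 361 were called without NPC_LPCs replicate 1. Of the 27 called genes chosen for naming, none kept its call in either case. By DESeq2's Wald test 1517 genes were called and by limma-voom 5, and every fold change in this comparison should be read with that range. In alternatives chosen after the data were seen, 63.2% of 57 calls were higher among genes taken as counted alike and 56.1% of 212 on FPKM. The balance of directions is therefore not settled.

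Lgals2, Cpne4 and Cobl were among the largest increases in Hep_LPCs. Lgals2, encoding galectin-2 (chromosome 15, 78850860 to 78855529), was at 593 ± 87.2 CPM against 8.18 ± 0.00301 CPM (log2 fold change 6.18 ± 0.31, adjusted p = 0.0128). Cpne4, a calcium-dependent phospholipid-binding protein, rose by 6.79 ± 0.45 (adjusted p = 0.0170), and Cobl, an actin nucleator, by 4.80 ± 0.34 (adjusted p = 0.0170). Fgfbp1, which carries fibroblast growth factors, rose by 5.84 ± 0.62, and Bco1, the enzyme that cleaves beta-carotene, by 4.47 ± 0.40 (adjusted p = 0.0315 for each). Cdx2, a transcription factor of intestinal epithelium (chromosome 5, 147300805 to 147307270), was at 31.1 ± 2.54 CPM against 3.88 ± 0.750 CPM (adjusted p = 0.0382). The gastrointestinal list was higher in Hep_LPCs (camera adjusted p = 7.83e-04), with 1 of 11 members called and 6 higher when adjusted over the list alone. It gave adjusted p = 0.713 with an estimated correlation. Lgals4, galectin-4 of gut epithelium, was not called at 20.6 ± 12.5 CPM against 1.81 ± 0.389 CPM (adjusted p = 0.0679).

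Oas3, Stat2 and Ifi27, genes of the interferon response, were lower in Hep_LPCs than in NPC_LPCs. Oas3, an enzyme of the double-stranded RNA response, was at 0.224 ± 0.00224 CPM in Hep_LPCs and 48.3 ± 40.2 CPM in NPC_LPCs (log2 fold change -7.71 ± 0.89, adjusted p = 0.0379). Stat2, a transcription factor of type I interferon signalling, fell from 153 ± 49.1 to 26.5 ± 5.13 CPM (-2.53 ± 0.33, adjusted p = 0.0470). Ifi27 fell to 1.65 ± 0.373 from 17.3 ± 0.404 CPM (adjusted p = 0.0455). Of 25 list members 6 were called lower and none higher, and 25 were lower when adjusted over the list alone. The median was -5.40, which did not move with the 2 members at 0 reads in Hep_LPCs set to the bound their depth allows (camera adjusted p = 5.23e-17). The list gave adjusted p = 0.713 with an estimated correlation, and 0.712 was the correlation estimated between its members. The NPC_LPCs replicates differed among themselves. Isg15, a ubiquitin-like protein made on interferon signalling, was at 5.08 CPM in replicate 1 and 104 CPM in replicate 2, with 0.0585 and 0.297 CPM in Hep_LPCs. These Isg15 levels are on the library sizes of the fit of 6.

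Fn1, Fbln2, Piezo2, Ulbp1, Angptl2 and Inhba were also lower in Hep_LPCs. Fn1, fibronectin, was at 1524 ± 121 CPM against 8559 ± 1243 CPM (-2.49 ± 0.29, adjusted p = 0.0376), and Fbln2, a matrix glycoprotein, fell by 2.36 ± 0.32 (adjusted p = 0.0472). Piezo2, a mechanosensitive ion channel, was at 0.140 ± 0.0382 CPM against 46.0 ± 32.8 CPM (-8.29 ± 0.82, adjusted p = 0.0315). Ulbp1, a ligand of the natural killer receptor NKG2D, changed by -8.47 ± 1.06 and Angptl2, a secreted angiopoietin-like protein, by -7.78 ± 0.64 (adjusted p = 0.0472 and 0.0240). Inhba, a subunit of activin, was at 7.10 ± 3.43 CPM against 359.6 ± 233 CPM (adjusted p = 0.0441). In the list of genes of epithelial to mesenchymal transition 1 of 19 members was called lower, Fn1, and 7 were lower and 1 higher when adjusted over the list alone (camera adjusted p = 0.0145). That call gave adjusted p = 0.713 with an estimated correlation, and was also lost without NPC_LPCs replicate 2 (adjusted p = 0.201) and without Hep_LPCs replicate 2 (0.139). The mesenchymal and stellate cell list was not called (camera adjusted p = 0.260), with 1 of 13 members called lower, Fbln2, and 6 lower and 2 higher when adjusted over the list alone.

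Zfp36 and Atf3, immediate early genes that respond within minutes to stress and growth signals, were higher in Hep_LPCs. Zfp36, a protein that destabilizes inflammatory mRNAs, was at 344 ± 41.9 CPM against 35.1 ± 3.72 CPM (3.30 ± 0.27, adjusted p = 0.0240), and Atf3, a stress-induced transcription factor, rose by 2.92 ± 0.27 (adjusted p = 0.0315). Their list, immediate early and dissociation, also holds heat-shock genes and can follow cell handling. Zfp36 and Atf3 were the 2 members called of 20, with 13 higher when adjusted over the list alone. The list's camera adjusted p was 1.04e-07, and adjusted p = 0.713 with an estimated correlation. The proliferation list was higher in Hep_LPCs by camera (adjusted p = 3.92e-06) with no single member called by edgeR, 14 of 30 at an unadjusted p under 0.05, 4 called by DESeq2 and none by limma-voom. It gave adjusted p = 0.741 with an estimated correlation, and 0 members were called when adjusted over the list alone. Mki67, the proliferation antigen Ki-67, was at 609 ± 322 and 481 ± 193 CPM, within the spread of the replicates (adjusted p = 0.701). The cilium list was lower in Hep_LPCs (camera adjusted p = 0.00322; adjusted p = 0.713 with an estimated correlation), with no member called by edgeR, 4 of 12 at an unadjusted p under 0.05, 3 called by DESeq2 and none by limma-voom, and 3 lower when adjusted over the list alone. Without NPC_LPCs replicate 2 the cilium call was lost (adjusted p = 0.0994). The list of WNT targets was higher in Hep_LPCs (camera adjusted p = 0.0196; adjusted p = 0.713 with an estimated correlation), with no member called by edgeR, 6 higher and 1 lower at an unadjusted p under 0.05, 4 and 1 called by DESeq2, none by limma-voom, and 2 higher and 1 lower when adjusted over the list alone. That call was lost without NPC_LPCs replicate 2 (adjusted p = 0.0963), without Hep_LPCs replicate 1 (0.260) and with genes any counting rule would count alike (0.0535).

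No biliary or progenitor marker was called by edgeR between these groups. Krt19, a keratin of bile duct cells, was at 1160.0 ± 389 CPM in Hep_LPCs and 193 ± 116 CPM in NPC_LPCs (2.59 ± 0.51, adjusted p = 0.0790). Sox9, a transcription factor of bile duct and progenitor cells, was at 112 ± 4.45 and 169 ± 123 CPM (adjusted p = 0.545), and Spp1, osteopontin, at 1965 ± 1499.9 and 6574 ± 3352 CPM (adjusted p = 0.212). Cd24a, a progenitor surface marker, was at 1154 ± 233 and 848 ± 232 CPM, and Cdh1, E-cadherin, at 802 ± 0.542 and 264 ± 224 CPM (adjusted p = 0.450 and 0.227). Of the 25 biliary markers 0 were called by edgeR, 5 were higher and 7 lower at an unadjusted p under 0.05, and DESeq2 called 4 higher and 4 lower and limma-voom 0. Adjusted over the list alone 1 biliary marker was higher and 2 were lower. Of the 16 progenitor markers 3 were higher and 3 lower at an unadjusted p under 0.05, DESeq2 called 2 higher and 2 lower and limma-voom 0, and 2 were higher and 2 lower when adjusted over the list alone. Ptprc, the leukocyte antigen CD45, had 2 and 5 reads in the NPC_LPCs libraries and 3 and 1 in the Hep_LPCs libraries, and Pecam1, an endothelial adhesion molecule, 1 read or none in each. Other cell-type markers were not near 0, with levels here on the library sizes of the fit of 6. Cd14, a monocyte receptor, was at 107 ± 76.8 CPM in NPC_LPCs and 66.5 ± 38.6 CPM in Hep_LPCs. Cd68, a macrophage lysosomal protein, was at 52.4 ± 44.5 and 18.4 ± 6.24 CPM, and Msln, mesothelin, at 420.4 ± 259 and 517 ± 437 CPM. None of these 3 was called. The 17 lists not called, adjusted p from 0.143 to 0.876, were urea cycle, xenobiotic and bile acid enzymes, biliary markers, progenitor markers, YAP targets, Notch, mesenchymal, endothelial, macrophage and mesothelial markers, NF-kB, cholesterol, lipid metabolism, glycolysis, p53, NRF2 and sex-linked genes. Median, mean and test differed in sign for the xenobiotic, Notch and glycolysis lists.

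**Figure D2:**
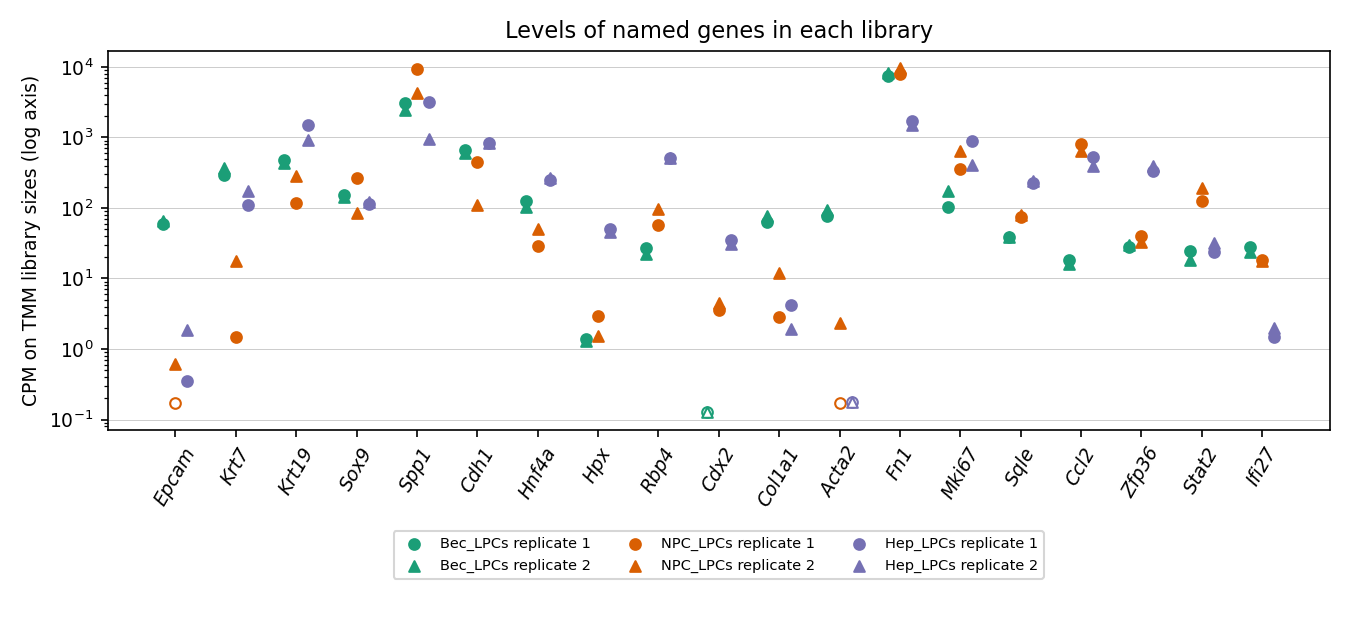
CPM on TMM library sizes, on a log axis, of 19 genes named in the text in each of the 6 libraries, with circles for replicate 1 and triangles for replicate 2. Open symbols lie below the level of 3 reads and are drawn at that level, and Acta2 in Hep_LPCs and Cdx2 in Bec_LPCs are among them.

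Bile duct-derived cells were set beside both other groups, and these comparisons differ in source tissue, sort and genotype and in how the tables were counted, all of which move together. Unless stated, counts of called list members in them can include genes that are not taken as counted alike. Against NPC_LPCs, Krt7, Cldn7 and Dcdc2a were higher in Bec_LPCs, while Krt19, Sox9 and Spp1 were not called. Krt7, a keratin of bile duct cells, was at 331 ± 46.9 CPM in Bec_LPCs and 9.59 ± 11.4 CPM in NPC_LPCs (5.10 ± 1.06, adjusted p = 0.0387). Hep_LPCs also carried these keratins, with Krt7 at 141 ± 46.4 CPM and Krt19 at 1221 ± 410 CPM, against 456 ± 21.8 CPM of Krt19 in Bec_LPCs. Cldn7, a tight junction claudin, was at 18.3 ± 6.19 CPM against 0 reads in both NPC_LPCs libraries, at least 113-fold higher against a floor of 3 reads per library (adjusted p = 0.0120), and Dcdc2a, a doublecortin-domain protein, rose by 3.75 ± 0.70 (adjusted p = 0.0303). Epcam, used for the sort, was at 62.3 ± 4.78 and 0.363 ± 0.350 CPM. Krt19, Sox9 and Spp1 gave no call (adjusted p = 0.135, 0.758 and 0.216), though Sox9 was called lower without NPC_LPCs replicate 2 (-0.87, adjusted p = 0.0457) and was at 0.77 without replicate 1. Without Epcam, left out after its values were seen, 3 of 26 biliary markers were called higher and 1 lower, 3 and 2 when adjusted over the list alone, and the list was called neither by camera (adjusted p = 0.476, or 0.326 with Epcam) nor by fry (0.104). In total 1460 of 12873 genes were called, 630 higher and 830 lower in Bec_LPCs (43.2% higher), and with library size alone in place of TMM 61.3% were higher, the median of all genes being 0.17 against 0.01 with TMM. Without Bec_LPCs replicate 1 115 genes were called (19.1% higher) and without replicate 2 117 (22.2% higher), so the balance of directions is not settled. Of 43 called genes chosen for naming 8 and 7 kept their call. There were 851 without NPC_LPCs replicate 1 (33.4% higher), and 2365 and 2348 without Hep_LPCs replicate 1 or 2. Genes taken as counted alike gave 710 calls, a value chosen for test after the tables were seen to differ.

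The mesenchymal and stellate cell list was higher in Bec_LPCs (camera adjusted p = 0.0218), with 5 of 18 members called higher and 1, Col6a2, lower, and 9 and 2 when adjusted over the list alone. It gave adjusted p = 0.769 with an estimated correlation. Acta2, smooth muscle actin (chromosome 19, 34241090 to 34255590), was at 85.8 ± 11.6 CPM against 1.17 ± 1.65 CPM (6.16 ± 1.30, adjusted p = 0.0492; all 46 reads of NPC_LPCs lay in replicate 2), and Col1a1, a fibrillar collagen chain, at 70.3 ± 9.29 against 7.49 ± 6.51 CPM (3.22 ± 0.72, adjusted p = 0.0447). Bgn, biglycan, rose by 4.76 ± 0.85 (adjusted p = 0.0273). Pdgfrb, a receptor of pericytes and stellate cells, was at 4.89 ± 0.656 CPM, with 1 read in NPC_LPCs. Grem1, a BMP antagonist, rose by 6.83 ± 0.52 and Ltbp2, a matrix protein that binds fibrillin, by 4.55 ± 0.65 (adjusted p = 0.00287 and 0.0165). The call on the list was lost without Bec_LPCs replicate 2 (adjusted p = 0.0885), without Hep_LPCs replicate 1 (0.0932) or 2 (0.0918), and with library size alone (0.0873). Macrophage transcripts were seen beside them at low levels: Lyz2, lysozyme, was at 12.2 and 14.4 CPM in the Bec_LPCs libraries and 0.318 ± 0.449 CPM in NPC_LPCs, and Ctss, cathepsin S, at 1.91 ± 0.580 CPM and 0. Of 8 macrophage genes 3 were called higher and none lower, and 3 higher and 1 lower when adjusted over the list alone. The macrophage list was not called by camera (adjusted p = 0.301) and was higher by fry (adjusted p = 0.0299).

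Ccl2, Cxcl1, Lcn2 and Saa3, genes of inflammation, were lower in Bec_LPCs than in NPC_LPCs. Ccl2, a monocyte chemokine, was at 17.3 ± 1.70 CPM against 726 ± 111 CPM (-5.39 ± 0.26, adjusted p = 9.28e-04), and Cxcl1, a neutrophil chemokine, at 36.7 ± 3.17 against 794 ± 231 CPM (-4.44 ± 0.27, adjusted p = 0.00145). Lcn2, lipocalin-2 of the acute phase, was at 0.656 ± 0.624 against 1259 ± 802 CPM (-10.89 ± 1.53, adjusted p = 0.0159). Saa3, an acute phase serum amyloid, had 0 reads in Bec_LPCs and was at 141 and 21.1 CPM in the NPC_LPCs libraries (adjusted p = 0.0254). Of 21 NF-kB and cytokine genes 10 were called lower and none higher, and 14 lower and 1 higher when adjusted over the list alone (camera adjusted p = 7.93e-07; adjusted p = 0.453 with an estimated correlation). Their median log2 fold change was -2.97, or -2.14 with members at 0 reads set at their bound. Interferon genes were lower too: Stat2 fell from 159 ± 48.2 to 21.4 ± 4.69 CPM (-2.90 ± 0.31, adjusted p = 0.00771), 11 of 25 members were called lower and 23 when adjusted over the list alone (camera adjusted p = 3.07e-08; adjusted p = 0.769 with an estimated correlation). Isg15 was at 5.08 CPM in NPC_LPCs replicate 1 and 104 CPM in replicate 2.

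Sqle, Egln3 and Tpx2 were lower in Bec_LPCs than in NPC_LPCs. Sqle, the squalene epoxidase of cholesterol synthesis, was at 38.2 ± 0.0861 against 76.0 ± 3.40 CPM (-0.99 ± 0.15, adjusted p = 0.0190). Of 24 cholesterol genes 7 were called lower and none higher, and 15 lower when adjusted over the list alone (camera adjusted p = 9.53e-07; adjusted p = 0.769 with an estimated correlation). Among 24 glycolysis and hypoxia genes 8 were called lower and 1 higher, and 16 and 3 when adjusted over the list alone (camera adjusted p = 8.02e-04; adjusted p = 0.769 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase, fell by 1.90 ± 0.25 (adjusted p = 0.0141). Gapdh, the member called higher at 2.70 ± 0.18, has 92 near-identical copies in the annotation and its value is uncertain. Of the 8 members called lower 4 are taken as counted alike, and the rest are uncertain too. In the proliferation list 3 of 30 members were called lower, Tpx2, Ube2c and Kif20a, of which Ube2c and Kif20a share exons or sequence with other genes and are uncertain. Adjusted over the list alone 10 were lower and 1 higher (camera adjusted p = 9.10e-05; adjusted p = 0.850 with an estimated correlation). The p53 and senescence list was higher (camera adjusted p = 0.0218; adjusted p = 0.769 with an estimated correlation), with 4 of 22 members called higher and 1, Cdkn1a, lower, 5 and 1 adjusted over the list alone, and Cdkn2a, the cell cycle inhibitor locus, at 112 ± 1.82 against 35.6 ± 2.15 CPM (adjusted p = 0.00512). That list was not called without NPC_LPCs replicate 1 (adjusted p = 0.0551).

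Snai1, of the list of epithelial to mesenchymal transition, was lower in Bec_LPCs than in NPC_LPCs. Snai1, a repressor of E-cadherin, was at 1.74 ± 0.702 against 18.1 ± 6.47 CPM (-3.38 ± 0.46, adjusted p = 0.0145). In this list 3 of 20 members were called lower and none higher, with the same counts adjusted over the list alone, and S100a4, a calcium-binding protein, is uncertain because it shares exons with a neighbouring gene. The list's camera adjusted p was 0.00681, and adjusted p = 0.769 with an estimated correlation. It was not called without NPC_LPCs replicate 2 (adjusted p = 0.0902). Hnf4a was higher in Bec_LPCs (1.52 ± 0.30, adjusted p = 0.0333) and Rbp4 lower (-1.63 ± 0.27, adjusted p = 0.0238), while Ambp, the precursor of alpha-1-microglobulin, was at 20.7 ± 4.28 against 0.112 ± 0.0865 CPM (adjusted p = 0.00944). Cdx2 was lower, with 4 reads in the 2 Bec_LPCs libraries together against 150 in NPC_LPCs (adjusted p = 0.00213). The 19 lists not called had adjusted p from 0.0570 to 0.987. They were cilium, macrophage, biliary, lipid metabolism, WNT, progenitor, endothelial, gastrointestinal, NRF2, MHC class II, hepatocyte identity, Notch, mesothelial, lymphocyte, xenobiotic, urea cycle, immediate early, YAP and sex-linked genes. By fry the Notch and MHC class II lists were higher (adjusted p = 0.0477 for each). Median, mean and test differed in sign for hepatocyte identity, urea cycle, Notch, lymphocyte, immediate early, MHC class II and sex-linked genes.

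Against Hep_LPCs, Hnf4a, Rbp4, Hpx, Lgals2 and Krt20 were lower in Bec_LPCs. Hnf4a was at 115 ± 15.4 CPM in Bec_LPCs and 255 ± 10.5 CPM in Hep_LPCs (-1.15 ± 0.29, adjusted p = 0.0308), Rbp4 fell by 4.39 ± 0.30 and Hpx by 5.16 ± 0.39 (adjusted p = 0.00134 and 0.00165). Of 13 hepatocyte identity genes 5 were called lower and 1, Ambp, higher, with the same counts adjusted over the list alone (camera adjusted p = 0.0443; adjusted p = 0.519 with an estimated correlation). Lgals2 was at 3.96 ± 0.585 CPM against 624 ± 92.1 CPM (-7.30 ± 0.25, adjusted p = 2.86e-04), Krt20, an intestinal keratin, at 33.9 ± 2.24 against 223 ± 22.2 CPM (adjusted p = 0.0123), and Cdx2 had 4 reads against 1112. The gastrointestinal list was not called by camera (adjusted p = 0.158) and was lower by fry (adjusted p = 0.0147), with 4 of 12 members called lower and 1, Krt17, higher. In total 4298 of 12873 genes were called, 2078 higher and 2220 lower in Bec_LPCs (48.3% higher), and with library size alone 60.9% were higher, the median of all genes being 0.21 against 0.031 with TMM. Without Bec_LPCs replicate 1 491 genes were called and without replicate 2 490, and 32 and 35 of 62 called genes chosen for naming kept their call. Genes taken as counted alike gave 3263 calls. The hepatocyte list was not called without Bec_LPCs replicate 2 (adjusted p = 0.0664) or Hep_LPCs replicate 1 (0.119).

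Acta2, Fn1, Fbln2, Lox and Col1a1 were higher in Bec_LPCs than in Hep_LPCs. Acta2 was at 85.8 ± 11.6 CPM against 0 reads in both Hep_LPCs libraries, at least 485-fold higher (adjusted p = 0.0144). Fn1 was at 7819 ± 525 against 1604 ± 128 CPM (2.29 ± 0.20, adjusted p = 0.00216) and Fbln2 rose by 2.58 ± 0.25 (adjusted p = 0.00280). Lox, the lysyl oxidase that cross-links collagen, was at 109.8 ± 20.8 CPM, with 1 read in Hep_LPCs, and Col1a1 rose by 4.51 ± 0.77 (adjusted p = 0.0114). Of 18 mesenchymal and stellate cell genes 10 were called higher and 1, Fbln1, lower, with the same counts adjusted over the list alone (camera adjusted p = 0.00376; adjusted p = 0.491 with an estimated correlation). Piezo2 was at 98.8 ± 13.5 against 0.147 ± 0.0403 CPM and Ulbp1 at 97.3 ± 1.38 against 0.147 ± 0.0403 CPM (adjusted p = 0.00216 and 0.00414). Jag1, a Notch ligand of the developing bile duct, was at 659 ± 16.4 against 84.5 ± 21.9 CPM (2.96 ± 0.34, adjusted p = 0.00425), in a Notch list with 3 members called higher, 3 lower and no call (camera adjusted p = 0.723). Pkd2, a calcium channel of the primary cilium, rose by 1.87 ± 0.19 and Pkhd1, fibrocystin, by 2.60 ± 0.37 (adjusted p = 0.00314 and 0.00732). In the cilium list 4 of 14 members were called higher and none lower, with the same counts adjusted over the list alone (camera adjusted p = 0.00135; adjusted p = 0.519 with an estimated correlation). Only 2 of these 4 members are taken as counted alike, and the rest are uncertain. Lyz2 was at 12.2 and 14.4 CPM in the Bec_LPCs libraries and 0.176 ± 0.165 CPM in Hep_LPCs, with 3 of 8 macrophage genes called higher and none lower, as also when adjusted over the list alone. The macrophage list was not called by camera (adjusted p = 0.0846) and was higher by fry (adjusted p = 0.0145).

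Mki67, Sqle, Cxcl1 and Zfp36 were lower in Bec_LPCs than in Hep_LPCs. Of 30 proliferation genes 23 were called lower and none higher, and 28 lower when adjusted over the list alone (camera adjusted p = 1.82e-08; adjusted p = 0.519 with an estimated correlation). Of these 23 genes 15 are taken as counted alike, and the rest are uncertain. Mki67 was at 139 ± 53.1 against 641 ± 339.8 CPM (-2.20 ± 0.51, adjusted p = 0.0238), and Tpx2, a spindle assembly factor, fell by 2.80 ± 0.35 (adjusted p = 0.00504). Sqle was at 38.2 ± 0.0861 against 234 ± 11.4 CPM (adjusted p = 8.87e-04), and 13 of 24 cholesterol genes were called lower and none higher, 20 lower when adjusted over the list alone (camera adjusted p = 5.35e-06; adjusted p = 0.519 with an estimated correlation). Among the 13 called, 10 are taken as counted alike. Cxcl1 was at 36.7 ± 3.17 against 1061 ± 48.2 CPM and Ccl20, a chemokine for dendritic cells and T cells, at 2.36 ± 0.177 against 214 ± 122 CPM (adjusted p = 8.62e-04 and 0.00456). The NF-kB list had 11 of 21 members called lower and none higher, as also when adjusted over the list alone (camera adjusted p = 2.83e-04; adjusted p = 0.491 with an estimated correlation). Zfp36 fell by 3.65 ± 0.20 (adjusted p = 8.13e-04). Of 20 immediate early and dissociation genes 11 were called lower and none higher, as also adjusted over the list alone. Among the 11 called, 8 are taken as counted alike. That list's camera adjusted p was 4.31e-04, and adjusted p = 0.519 with an estimated correlation.

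Ifi27 and Bst2, genes of the interferon response, were higher in Bec_LPCs than in Hep_LPCs. Ifi27 was at 25.9 ± 3.14 against 1.74 ± 0.392 CPM (3.89 ± 0.29, adjusted p = 0.00153), and Bst2, a membrane protein that tethers virions, rose by 1.71 ± 0.45 (adjusted p = 0.0337). Of 25 members 5 were called higher and none lower, and 1 higher when adjusted over the list alone (camera adjusted p = 0.00383; adjusted p = 0.700 with an estimated correlation). Their median was 2.06, or 2.02 with members at 0 reads set at their bound. By fry the interferon list was not called (adjusted p = 0.115). Lect2, a secreted hepatocyte protein in the list of WNT targets, fell by 3.71 ± 0.33 and Axin2, a feedback inhibitor of WNT signalling, by 0.89 ± 0.21 (adjusted p = 0.00236 and 0.0252). In that list 7 of 16 members were called lower and 1, Slc1a2, higher, 10 and 1 adjusted over the list alone (camera adjusted p = 0.0139; adjusted p = 0.519 with an estimated correlation), and the call was lost without Hep_LPCs replicate 1 (adjusted p = 0.227). In the glycolysis list 10 of 24 members were called lower and 2, Gapdh and Car9, higher, 11 and 2 adjusted over the list alone (camera adjusted p = 0.00864; adjusted p = 0.519 with an estimated correlation). That call was lost without Hep_LPCs replicate 2 (adjusted p = 0.0595) and with genes any counting rule would count alike (0.134). Of the glycolysis members called, 3 of the 10 lower and 1 of the 2 higher are taken as counted alike, and the rest are uncertain. Ndrg1, a hypoxia-induced gene, fell by 3.68 ± 0.42 (adjusted p = 0.00417). Without Epcam 4 of 26 biliary markers were called higher and 1, Elf3, lower, as also when adjusted over the list alone, and the list was not called by camera (adjusted p = 0.316, or 0.249 with Epcam) and was higher by fry (0.0284). The 17 lists not called, these biliary markers among them, had adjusted p from 0.0846 to 0.994. They were lipid metabolism, p53, macrophage, MHC class II, gastrointestinal, biliary, urea cycle, sex-linked, NRF2, mesothelial, YAP, lymphocyte, Notch, xenobiotic, epithelial to mesenchymal transition, progenitor and endothelial genes, and median, mean and test differed in sign for the progenitor and endothelial lists. By fry the p53 and MHC class II lists were higher too (adjusted p = 0.0397 and 0.0130).

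**Figure D3:**
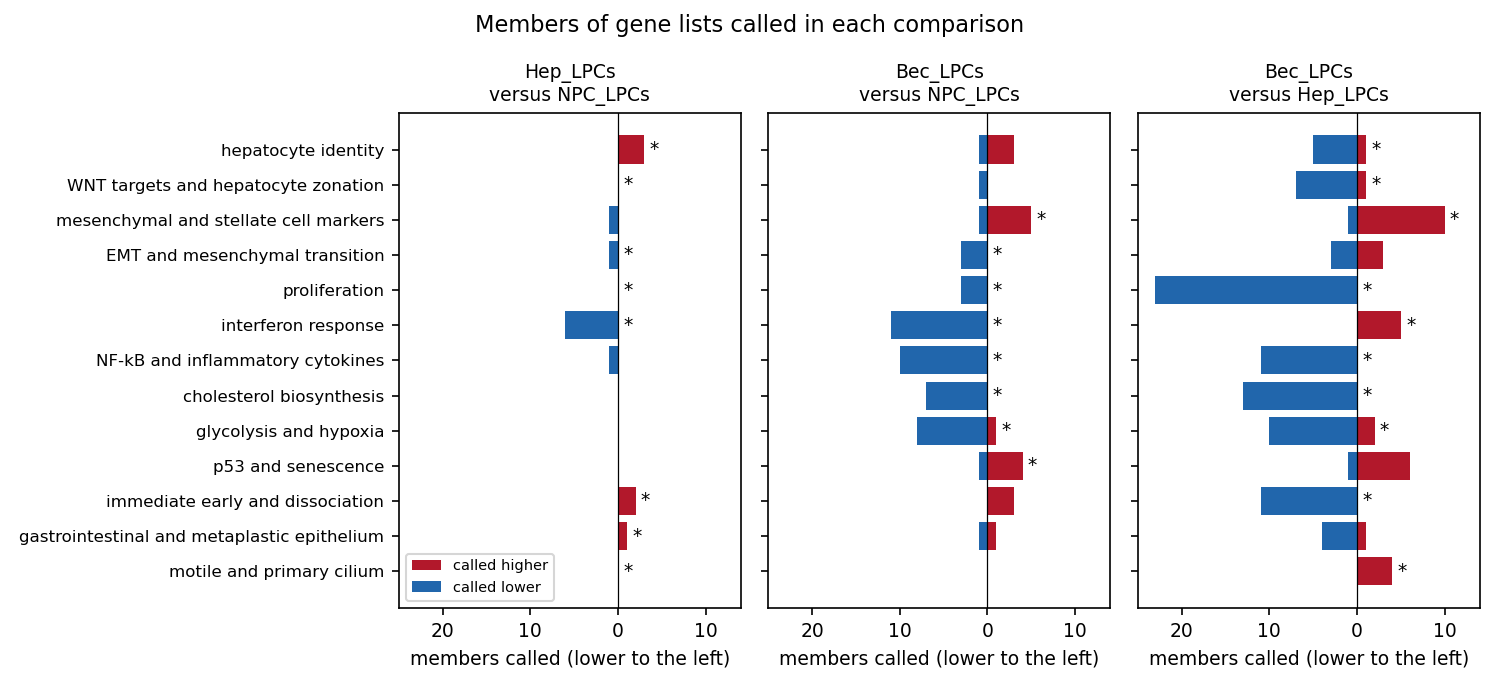
Number of list members called higher (right) and lower (left) in each of the 3 comparisons, for each list called in at least 1 of them, with an asterisk where camera with the preset correlation called the list. The longest bar is proliferation in Bec_LPCs against Hep_LPCs, with 23 members called lower.

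Genes that part bile duct-derived from hepatocyte-derived cells were compared with those that part non-parenchymal-derived from hepatocyte-derived cells. Fn1 was higher than in Hep_LPCs in both Bec_LPCs (7819 ± 525 CPM) and NPC_LPCs (8881 ± 1134 CPM, against 1604 ± 128). Likewise Lgals2 was at 3.96 ± 0.585 CPM in Bec_LPCs and 8.49 ± 0.154 CPM in NPC_LPCs, against 624 ± 92.1 CPM in Hep_LPCs, all on the library sizes of the fit of 6. In the fit of all 6 libraries 466 genes were called higher than in Hep_LPCs in both other groups, 471 lower in both and 12 in opposite directions. This rests on 1275 calls between NPC_LPCs and Hep_LPCs in that fit, which takes part of its spread from the Bec_LPCs libraries, against 98 in the fit of the 4 libraries compared. Independent lists of these sizes would share 106 and 107. In 40 simulations of unchanged groups that shared the Hep_LPCs libraries, a mean of 0.0250 genes were higher in both and 0 lower. The first value leaves out the shared libraries and the second the effects, so neither excess measures a shared effect. The fold changes correlated across genes at r = 0.599, against 0.625 in the simulations, and their covariance was 1.70 against 0.164, a difference of 1.53. These values are not over the same genes. The simulations drew every group at its Hep_LPCs level, and a mean of 12039 genes passed the filter there, against 12873 in the data. The 2 Hep_LPCs libraries cannot be split into 2 sets of at least 2, so part of the excess may come from the shared libraries. The shared count was 937 with all libraries, 80 and 64 without Bec_LPCs replicate 1 or 2, and 460 without NPC_LPCs replicate 2.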

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

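The tests of explanations in this part were all chosen after the results were seen. Mitochondrially encoded genes, which the comparisons do not use, held 4.19% and 4.26% of the counts of Bec_LPCs replicates 1 and 2, a signal in data outside the main measurement, and they have no entry in the other tables. Within them mt-Co1 had 321329 reads and mt-Co2 496 in replicate 1.

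There were 31 broadly expressed genes near 0 in the Bec_LPCs tables, such as Raver1 (154 CPM in NPC_LPCs, 0 reads in Bec_LPCs) and Tomm6 (189 CPM in NPC_LPCs). Of the 30 with an annotated overlap value, 26 (86.7%) share over 25% of their exonic length with another protein-coding gene, against 3.20% of 9085 other expressed genes (Fisher's exact test p = 1.04e-34). This is consistent with reads in shared exons having been counted in the NPC_LPCs and Hep_LPCs tables and not in the Bec_LPCs tables. Reads lost to near-identical copies cannot be told apart as a cause for the rest, since 2 of only 4 genes within this 25% limit have a copy. Ccdc22, among these 4, shares 17.2% of its exonic length. Genes of this set with over 25% overlap are therefore no evidence about the cells, and the cause for the others stays open.

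Interferon response genes were higher in NPC_LPCs than in Hep_LPCs, and more so in NPC_LPCs replicate 2, though a single library as the carrier is argued against, since 25 of 25 genes were higher in each NPC_LPCs library than in both Hep_LPCs libraries. Leukocytes that carry these 7 transcripts are argued against: Ptprc, Laptm5, Tyrobp, Fcer1g, Cd74, Ctss and Lyz2 together were at 1.36 CPM, 0.0834% of the summed interferon excess of 1629 CPM. Cells that carry most of the macrophage list are argued against as well. Of its 22 members 18 were under 1 CPM in both NPC_LPCs libraries. The median over the 22 was 0.0271 CPM, 0.0548% of the median interferon excess of 49.5 CPM. The sum of that list, tried before its median, does not argue against macrophage-type cells. It was 167 CPM (10.2% of the summed excess, and 4.83% of it after subtracting Hep_LPCs). Of this Cd14 and Cd68 held 159 CPM, and these were at 84.9 CPM in Hep_LPCs too. The median takes no account of those 2 genes, so cells that carry few other members of the list stay open. Also open are the cell source, the mouse line, the virus described for Hep_LPCs, a few cells that secrete interferon, and the culture, none of which these tables separate.

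Mesenchymal transcripts were higher in Bec_LPCs. All 10 members called higher than in Hep_LPCs (100%) share at most 25% of their exonic length with another protein-coding gene and have no near-identical copy. The same holds for all 18 tested members of the list, so this share was fixed in advance. It cannot decide whether a difference in counting between the tables played a part. Carried-over fibroblasts that express Dcn and Lum are argued against, since both together reached 0.0605% of the Col1a1 level. Smooth muscle or pericyte-type cells cannot be told apart, because 5 of 6 markers were higher in both Bec_LPCs libraries than in all 4 others while Tagln reached only 1.51% of Acta2. The sort on Epcam would act against such cells. A program of the duct-derived cells themselves also stays open, and was not tested.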

How the results depend on the processing

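No test in this part was chosen after the results were seen except the FPKM fit, the genes counted alike under any rule and the biliary list without Epcam, which left the number of list calls as it was; the cause of a change was not tested unless named. The labels give replicate numbers shared by the groups. Same-numbered libraries did not deviate together (correlation 0.0866, -0.0395 and -0.00855), and with the replicate block 128, 773 and 3396 genes were called in Hep_LPCs against NPC_LPCs, Bec_LPCs against NPC_LPCs and Bec_LPCs against Hep_LPCs. Called genes in Hep_LPCs against NPC_LPCs numbered 515 with no filter, 172 with the stricter filter, 1517 by DESeq2, 5 by limma-voom, 1275 with all 6 libraries in the fit, 57 among counted-alike genes and 212 on FPKM. In Bec_LPCs against NPC_LPCs they numbered 2897 by DESeq2, 2494 with only the 4 libraries compared and 710 among counted-alike genes. With 1 library left out, its lone partner assumed to vary like the other groups, the counts ranged from 0 to 361, 115 to 2365 and 490 to 4910 in the 3 comparisons in that order, list calls from 6 to 14, 7 to 9 and 10 to 12, and the overlap from 64 to 1044. No list kept its call with an estimated correlation (0 in each comparison). That loss cannot be put down to correlation alone, since camera then also rests on few residual degrees of freedom. Hepatocyte identity in Hep_LPCs against NPC_LPCs had an estimated correlation of -0.0545, below the preset 0.01. Its unadjusted p by camera still rose from 3.27e-04 to 0.0637. By fry 0 lists were called in Hep_LPCs against NPC_LPCs, 7 in Bec_LPCs against NPC_LPCs and 14 in Bec_LPCs against Hep_LPCs, against 8, 8 and 10 by camera with the preset correlation. Mean r, for Bec_LPCs with NPC_LPCs, Bec_LPCs with Hep_LPCs and NPC_LPCs with Hep_LPCs, was 0.855, 0.800, 0.875 with a prior of 0.5, 0.892, 0.844, 0.900 with a prior of 5, 0.941, 0.916, 0.944 with no filter, 0.794, 0.695, 0.819 with the stricter filter, 0.916, 0.868, 0.914 by Spearman, and 0.898 and 0.837 for the first and the second among counted-alike genes. Log2 fold changes turned sign in 5 cases, none of them called with or without the library. With 1 library left out, Sox9 in Hep_LPCs against NPC_LPCs ranged from -1.19 without NPC_LPCs replicate 2 to 0.48 without NPC_LPCs replicate 1, and in Bec_LPCs against NPC_LPCs from -0.87 (called, adjusted p = 0.0457) to 0.77 without the same libraries. Mki67 in Hep_LPCs against NPC_LPCs ranged from -0.32 without Hep_LPCs replicate 1 to 0.82 without NPC_LPCs replicate 2, and was -0.0017 without NPC_LPCs replicate 1. Spp1 in Bec_LPCs against Hep_LPCs ranged from -0.20 without Hep_LPCs replicate 2 to 1.54 without Hep_LPCs replicate 1. Over all alternatives, called named genes kept the call in 1888 values and lost it in 301, uncalled ones gained it in 44, and 5 values turned. Single lists kept it in 240 and lost it in 56. Of the 27 named genes called in Hep_LPCs against NPC_LPCs 0 kept the call without either Hep_LPCs library, 2 kept it by limma-voom. Of 43 in Bec_LPCs against NPC_LPCs 8 and 7, and of 62 in Bec_LPCs against Hep_LPCs 32 and 35, kept it without Bec_LPCs replicate 1 or 2. Alternatives that change a pseudocount did not apply to counts.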

Other observations

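The genes of this part were chosen after their values were seen, and levels alone are given. Genes were taken as confined to a group with at least 5 CPM in both of its libraries and under 0.5 CPM in each of the other 4. At these levels 28 genes met this in Bec_LPCs, 2 in NPC_LPCs and 8 in Hep_LPCs, and 22, 2 and 8 of them are taken as counted alike. A difference in counting between the tables can also give such genes, and was not tested for them. Among the 22, Setdb2 had 292 and 283 reads in the Bec_LPCs libraries and Lrfn4 495 and 499, with at most 1 read in any other library. The numbers of genes per group are therefore no measure of the cells alone. Esrp1, a splicing regulator of epithelial cells, was at 21.7 ± 3.25 CPM in Bec_LPCs, and Ap1m2, an epithelial sorting adaptor, at 7.67 ± 2.73 CPM with 0 reads in the other 4 libraries. Others were the smooth muscle actin gene Actg2 (7.21 ± 0.712 CPM), the leukocyte genes Cd53 (5.23 ± 0.122 CPM) and Cytip (7.51 ± 0.895 CPM), and the stromal genes Mrc2, Adamts12 and Pappa, so they share no single cell type. Close to these levels were Grhl2, an epithelial transcription factor, at 7.11 ± 0.740 CPM against 0.0543 ± 0.00489 and 0.414 ± 0.337 CPM in NPC_LPCs and Hep_LPCs, and Rab25, an epithelial Rab GTPase, at 4.78 ± 0.0370 CPM against 0.159 ± 0.0621 and 0.208 ± 0.294 CPM. Cdh1, E-cadherin, was present in all 3 groups, at 632 ± 42.4, 277 ± 238 and 844 ± 0.947 CPM, and Esrp2, the paralog of Esrp1, at 26.1 ± 1.33, 19.9 ± 6.11 and 58.6 ± 1.61 CPM. Prdm16, a transcriptional regulator, was at 13.0 ± 2.08 CPM in Bec_LPCs with 0 reads in the others.

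The genes confined to Hep_LPCs were Acan, Cbln3, Cdhr5, Clic5, Cntnap5a, Ddc, En2 and Mettl7b, and none is in the gastrointestinal list. Cdhr5, a cadherin of the microvillar brush border, was at 22.1 ± 10.9 CPM with 0 reads in the other 4 libraries, and Ddc, the decarboxylase of aromatic amino acids, at 21.8 ± 7.96 CPM. Gcnt3, a mucin-type glycosyltransferase that did not meet these levels, was at 20.2 ± 5.28 CPM against 1.77 ± 0.350 and 0.236 ± 0.170 CPM in Bec_LPCs and NPC_LPCs. Acan, the cartilage proteoglycan aggrecan, differed between the Hep_LPCs replicates, at 137 and 12.7 CPM. Pax2, a transcription factor of kidney and duct development, was at 112 ± 88.4 CPM in Hep_LPCs and 22.1 ± 20.2 in NPC_LPCs. The Y-linked genes Kdm5d, Uty and Eif2s3y were at 0, 0.0593 and 0.0593 CPM in Hep_LPCs replicate 2 and at 49.9, 24.3 and 64.6 CPM in replicate 1.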
